A study of Mus musculus with 12 samples.

How the data were processed

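Chromatin of minced, formalin-fixed whole mammary glands was sheared to 300 to 500 bp and precipitated with antibodies against ERα or PR, with 4 µg of antibody for 30 µg of chromatin, per the labels' protocols. The labels gave the genotype, receptor and replicate number of each library, and the peak lists of 8 libraries were used: 2 each for ERα in WT, ERα in Y541S, PR in WT and PR in Y541S. The 4 samples with D542G were not analysed here. The series gives 2 biological replicates per condition, without saying how many animals each held. Exact permutation p-values of library values therefore rest on the spread between these libraries. The p-values of gene lists and of Fisher's exact tests come from genes or regions with the libraries held fixed, and do not cover that spread. The genotype could not be checked from peak positions.

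The authors deposited 1 peak list per library, so replicates were not pooled. The genome build was mm10, per the submitters' processing notes. The aligner, the peak caller, their versions and any use of input DNA were not given in the sources used here. Each deposited peak had a whole-number score that followed its p-value, a fold enrichment at its summit (a ratio of coverage to local expectation, without scaling between libraries), a −log10 p and a −log10 q. Every deposited −log10 p was at least 2. These are the authors' values, and they served to describe, rank or filter peaks within a list, because peak heights were not normalised across libraries. Only the median fold of the strongest peaks is also set side by side between libraries, without a test. A longer list can follow from depth, from the efficiency of precipitation or from binding, and a region absent from a list can hold signal below the threshold.

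The deposited fold and −log10 p of each peak were used to recover the whole-number coverage at the summit and its local expectation, with a tolerance of 1e-04 on −log10 p, which succeeded for 99.9956% of the peaks in the list where it was lowest. The lowest expectation (its 0.001 quantile) was taken as the background coverage. It was 2.39 and 1.30 for replicates 1 and 2 of ERα in WT, 2.29 and 1.72 for ERα in Y541S, 2.68 and 0.927 for PR in WT and 2.45 and 1.35 for PR in Y541S. Intervals on shares are 95% Wilson intervals and cover counting error only.

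Overlapping peaks (at least 1 bp) of the 4 libraries of a receptor were merged into regions. A region was Y541S-only with a peak in both Y541S and no WT library, WT-only in the reverse case and shared with a peak in all 4. It was reproducible in a genotype with a peak in both replicates. The same counts were made for the other ways of pairing the 4 libraries. Peak numbers were compared on the log2 scale with two-sided exact permutation tests of genotype within receptor, with 6 arrangements for 1 receptor and 36 for both, which cannot give a p below 0.33 and 0.0556. ERα peaks overlapping a PR peak of the same genotype and replicate number were compared in the same way. The 36 arrangements permute genotype separately for each receptor. The labels do not say whether the ERα and PR libraries of a replicate came from the same chromatin. If they did, the libraries are not independent, and p-values over both receptors are too small. Coincidence of Y541S-only regions of both receptors was tested with a two-sided Fisher's exact test over regions merged from all 8 libraries.

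Genes came from a RefSeq gene table of the assembly equivalent to mm10, with gene starts and ends but without transcripts or sequence, giving 21887 coding genes. The planned distances to transcription start sites were therefore replaced by distances to the gene's span or to either of its ends, exons and introns were not separated, and the planned motif counts were not run. A region was linked to every coding gene within 50 kb of its midpoint. The 12 gene lists (estrogen response, progesterone paracrine, progestin and glucocorticoid response, hormone-sensing luminal, luminal progenitor and alveolar, basal and myoepithelial, adipocyte, fibroblast and endothelial, immune, cell cycle, nuclear receptor coregulators and circadian clock) held 244 entries for 228 genes, all matched, 2 by synonym. The lists, tests, planned settings and the rule for named genes were fixed before the data were examined. For each list, the number of genes with a Y541S-only region was compared with 10000 random lists matched on the number of linked regions, two-sided, with Benjamini-Hochberg adjustment over 24 tests.

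Named genes were, for each receptor, Esr1, Pgr, Greb1, Areg, Tnfsf11 and Wnt4; examples from the up to 4 members of each list with most Y541S-only regions; the genes closest to the 8 Y541S-only and 4 WT-only regions best ranked in both of their libraries; and those closest to the 4 best-ranked shared regions. Genes named as the members of a small count of bound genes, and the genes of the closing section, were chosen after their values were seen.

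Alternatives were −log10 q of at least 1.3, −log10 p of at least 5, lists of the 20000 strongest peaks, overlap of at least 50% of the shorter interval, windows of 150 bp on each side of summits, link windows of 10 and 100 kb, a gene-end window of 5 kb, exact tests within replicate number and each library left out. After the data were seen, a setting was added in which coverage and expectation were scaled to the shallowest library and peaks kept at −log10 p of at least 5, also with 1 ERα library left out for co-occupancy. Scaled coverage was rounded down to whole reads, and the shallowest library was left unchanged by this. Equally long lists and left-out libraries for gene ends and gene lists, WT-only regions for gene lists, regions with a peak of both receptors, and all alternatives for the share outside genes were also added then. The region, coverage and list computations were run on simulated data, which checks the code and says nothing of these libraries. Well separated simulated regions, present in every library of their class, were recovered in full. So were 2962 of 2962 summit coverages, made with the same formula that the recovery inverts. A planted list of 20 genes among 21887 was detected, most of its genes having been drawn from those with a Y541S-only ERα region. Of 100 random lists, 5 had a p below 0.05. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.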

Results

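The estrogen receptor ERα, encoded by Esr1, and the progesterone receptor PR, encoded by Pgr, were mapped on chromatin by ChIP-seq in whole mammary glands of mice with wild-type Esr1 (WT) or with Esr1 carrying Y541S, a substitution in the ligand-binding domain of ERα. Mice were kept to 8 weeks of age and received estradiol and progesterone implants, and glands were taken 4 days later. The comparison asked how the 2 receptors meet chromatin in wild-type and mutant glands. There were 2 biological replicates for each receptor and genotype, 8 libraries in all, and the D542G samples of the series were not analysed here. The deposited lists held 64488 to 113695 peaks per library. The expected background coverage behind the peaks, a measure of depth recovered from the deposited values, ran from 0.927 in WT PR replicate 2 to 2.68 in WT PR replicate 1. The series title names luminal cells, whereas the sample labels and protocols give whole glands, which contain luminal, basal, fat, stromal and immune cells. A peak does not show which cells it came from, and the counts for markers of other cell types depend on which description holds.

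Of the genes examined for both receptors, Esr1, Greb1, Pgr and Tnfsf11 had ERα regions in all 4 ERα libraries, and Wnt4 and Areg had none. Greb1, an estrogen-induced growth regulator gene on chromosome 12, had 13 ERα regions present in all 4 libraries, the best ranked lying within the gene at 16760237 to 16760858, besides 1 region in both WT and neither Y541S library and 0 in the reverse case, with 16 regions found in both replicates in WT and 14 in Y541S. Esr1 had 6 ERα regions in all 4 libraries, 2 present in both Y541S and neither WT library and 2 in the reverse case. Pgr, on chromosome 9, had 4 such regions, the best ranked at 8970080 to 8970942, 1.90 kb outside the gene. Tnfsf11, which encodes the paracrine signal RANKL, had 2 regions in all 4 libraries, the better ranked at 78346882 to 78347181 on chromosome 14. Wnt4, a secreted ligand of mammary side branching, had 1 region in both Y541S and neither WT library, inside the gene on chromosome 4 at 137287934 to 137288289. Areg, a ligand of the EGF receptor, had no ERα region of any of these classes, with 2.50 ± 0.707 linked regions per WT library and 4.50 ± 0.707 per Y541S library (SD, n = 2).

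ERα regions found in both Y541S libraries and in neither WT library (Y541S-only regions) numbered 9843, against 1385 found in both WT and neither Y541S library (WT-only regions) and 19612 present in all 4. Among the Y541S-only regions ranked highest in both Y541S lists were one within Plxnd1, a semaphorin receptor gene, on chromosome 6 at 115995017 to 115995373, and one within Stat5b, a transcription factor gene of cytokine and prolactin signalling, on chromosome 11 at 100855561 to 100856149. Others lay 2.54 kb from Atp13a2 (chromosome 4, 140983469 to 140983885), 16.6 kb from Kl (chromosome 5, 151010274 to 151010633), 0.042 kb from Eif4ebp2 (chromosome 10, 61452702 to 61452961), 7.23 kb from Gm8439 and 140 kb from Krr1, and 1 was 1581 kb from its closest coding gene, Rpia. The highest-ranked WT-only regions lay within Thsd7a (chromosome 6, 12376175 to 12376562), 22.2 kb outside Esr1 itself (chromosome 10, 4589700 to 4589933), 9.02 kb from Whrn and 76.7 kb from Gm46240. The best-ranked regions shared by all 4 libraries lay within Zfp827, Gm12248 and Ccdc6 and 169 kb from Rybp, and each was among the first 12 peaks of every list.

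WT libraries held 68527 ± 5712 ERα peaks and Y541S libraries 106269 ± 929 (SD, n = 2), a 1.55-fold difference in geometric means (log2 0.64, SE 0.09). The fold was 1.47 within replicate 1 and 1.64 within replicate 2, which were also separate runs by the codes of the deposited files. Both Y541S values lay above both WT values, and the two-sided exact permutation p of 0.33 is the smallest that 2 against 2 libraries allow. Of the 24742 regions found in both WT libraries, 79.3% were also in both Y541S libraries, while 46.3% of the 42389 regions found in both Y541S libraries were in both WT libraries. Y541S-only regions sat in the middle of the Y541S lists, at a median rank of 51.5% and 46.0% of the list, and shared regions near the top, at 13.5% and 12.6%. Of 7287 regions with −log10 p of at least 10 in both Y541S libraries, 26 had no WT peak at all (0.357%, 95% Wilson interval 0.244 to 0.522%), and of 3123 such regions in WT, 0 had no Y541S peak (upper bound 0.123%).

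The counts of genotype-specific ERα regions depended strongly on the settings. In equally long lists of the 20000 strongest peaks there were 1445 Y541S-only and 697 WT-only regions, at −log10 p of at least 5 there were 4386 and 586, and with coverage scaled to the shallowest library there were 1644 and 223. Within replicate 1 alone the counts were 66715 and 31710, and within replicate 2 alone 78750 and 36725. Leaving out 1 library loosens both definitions, since presence in, or absence from, that genotype then rests on its other library alone: the counts became 19182 and 30042 without WT replicate 1, 13482 and 26576 without WT replicate 2, 65263 and 4104 without Y541S replicate 1, and 59596 and 2471 without Y541S replicate 2. Grouping the same 4 libraries by replicate number instead of genotype gave 7616 regions in replicate 1 only and 2449 in replicate 2 only, and the crossed grouping gave 3252 and 2943.

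**Figure D1:**
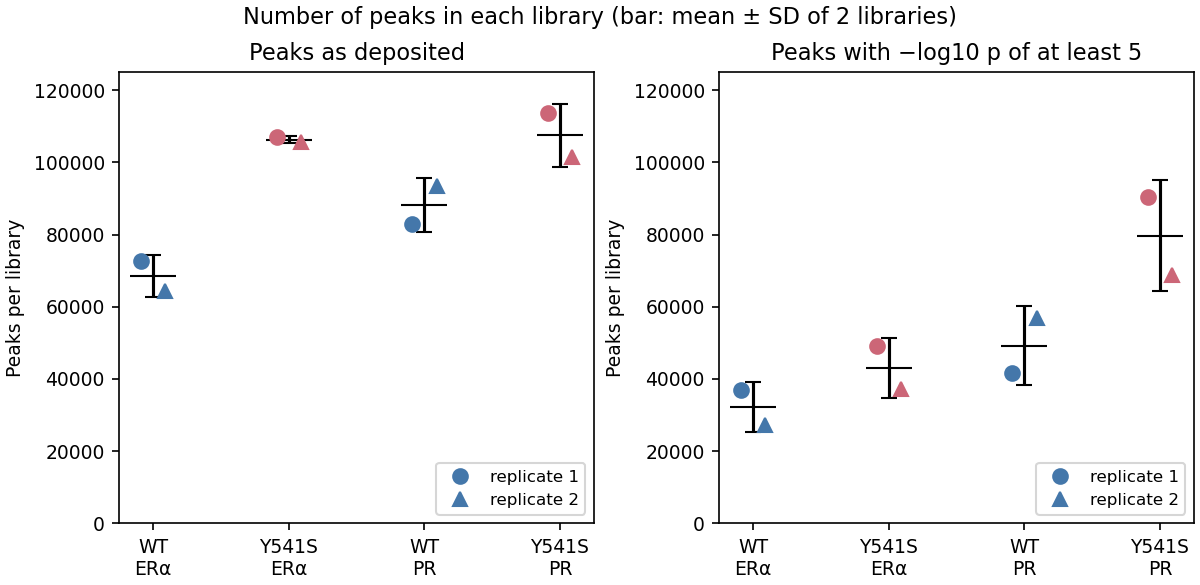
Number of peaks in each library (y axis) by genotype and receptor (x axis), as deposited and at −log10 p of at least 5; circles and triangles are replicates 1 and 2, and black bars give the mean ± SD of 2 libraries. As deposited, ERα means were 68527 (WT) and 106269 (Y541S), and at the stricter threshold the largest value was 90495, in Y541S PR replicate 1.

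Esr1, Pgr, Greb1, Areg, Tnfsf11 and Wnt4 each had PR regions in all 4 PR libraries. Tnfsf11 had 6 PR regions in all 4 libraries, the best ranked on chromosome 14 at 78346760 to 78347326, 39.0 kb outside the gene, with deposited fold enrichments of 14.3 and 19.2 in WT and 17.4 and 16.1 in Y541S. Wnt4 had 7 PR regions in all 4 libraries and 3 Y541S-only regions, and Greb1 had 11 and 3. Esr1 had 13 shared and 7 Y541S-only PR regions, with 26.0 ± 12.7 linked regions per WT library and 39.0 ± 12.7 per Y541S library (SD, n = 2). Areg had 3 shared and 2 Y541S-only PR regions, one of the latter on chromosome 5 at 91166505 to 91166952, and Pgr had 3 and 1, with 11 ± 1.41 linked PR regions per WT and 10 ± 2.83 per Y541S library. None of the 6 genes had a WT-only PR region.

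PR had 13325 Y541S-only, 1075 WT-only and 38120 shared regions. The Y541S-only regions ranked highest in both Y541S lists included one within Mylk, the myosin light chain kinase gene of contractile cells, on chromosome 16 at 34821622 to 34822104, with fold enrichments of 14.5 and 12.3. Most others lay far from coding genes: 250 kb from Tshz1 (chromosome 18, 83761125 to 83761587), 356 kb from Tfec (chromosome 6, 16474850 to 16475457), 157 kb from Ddx10 (chromosome 9, 52941523 to 52942131), 118 kb from Csmd3, 189 kb from Tle1, 351 kb from Mgmt and 114 kb from Ss18. The highest-ranked WT-only PR regions lay within Luzp1 (chromosome 4, 136524291 to 136524691), 3.82 kb from Mical3, 57.9 kb from Tmem252 and 34.0 kb from Gnat3. The best-ranked shared PR regions lay within Pkhd1, Nek7, Fhad1 and Patl2, each among the first 22 peaks of every list. Of 29689 regions with −log10 p of at least 10 in both Y541S libraries, 929 had no WT peak (3.13%, 95% Wilson interval 2.94 to 3.33%), against 1 of 12172 in the reverse direction.

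WT libraries held 88237 ± 7431 PR peaks and Y541S libraries 107538 ± 8707 (SD, n = 2), a 1.22-fold difference in geometric means (log2 0.29, SE 0.12). The fold was 1.37 within replicate 1 and 1.08 within replicate 2, and the two-sided exact permutation p of 0.33 is the smallest possible. Of the 42856 regions found in both WT libraries, 88.9% were in both Y541S libraries, and 54.1% of the 70417 regions found in both Y541S libraries were in both WT libraries. Median ranks were 60.9% and 60.2% of the Y541S lists for Y541S-only regions and 19.4% and 22.1% for shared ones. At −log10 p of at least 5 the fold was 1.62. With coverage scaled to the shallowest library it was 1.90 (exact permutation p = 1), made up of 4.36 within replicate 1 and 0.831 within replicate 2, where its direction turned. The shallowest library was WT PR replicate 2, which kept all its 56974 peaks at that threshold. In the other libraries scaled coverage was rounded down to whole reads, which lowers their counts, and the part of this in the turn was not tested. Over both receptors, the mean log2 difference in peak number was 0.46, with an exact permutation p of 0.0556, the smallest that 36 arrangements allow. This p treats ERα and PR libraries as independent. If those of a replicate shared chromatin, which the labels do not say, genotype would have to be permuted jointly. The smallest possible p would then be 0.33. With scaled coverage the mean log2 difference was 0.71, no longer the most extreme arrangement (exact permutation p = 0.222). As deposited, the ERα and PR effects differed by 0.35 (exact permutation p = 0.444).

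Genotype-specific PR regions were likewise sensitive to the settings. Equally long lists gave 1284 Y541S-only and 973 WT-only regions, −log10 p of at least 5 gave 12282 and 245, and scaled coverage gave 5927 and 21. Within replicate 1 alone the counts were 62460 and 30048, and within replicate 2 alone 45241 and 36517. They were 19203 and 25890 without WT replicate 1, 26567 and 27880 without WT replicate 2, 37950 and 4196 without Y541S replicate 1, and 41764 and 1637 without Y541S replicate 2. Other groupings of the 4 PR libraries gave 3876 and 3478 regions by replicate number and 1154 and 6486 when crossed, the larger of the crossed values belonging to WT replicate 2 with Y541S replicate 1.

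**Figure D2:**
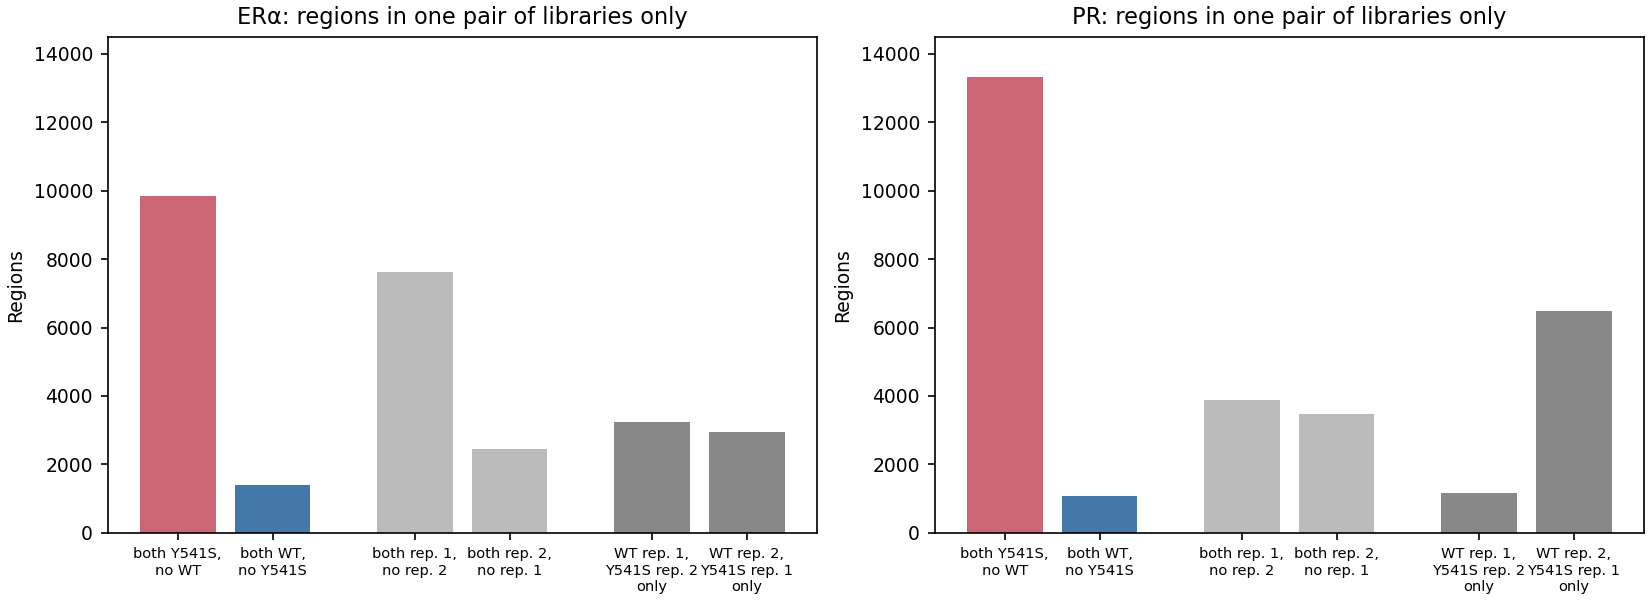
Number of regions (y axis) found in both libraries of one pair and in neither library of the other, for each way of pairing the 4 libraries of a receptor. The Y541S-only bars, 9843 for ERα and 13325 for PR, are the tallest, and the next tallest are 7616 for ERα and 6486 for PR, from groupings that mix the genotypes.

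**Figure D3:**
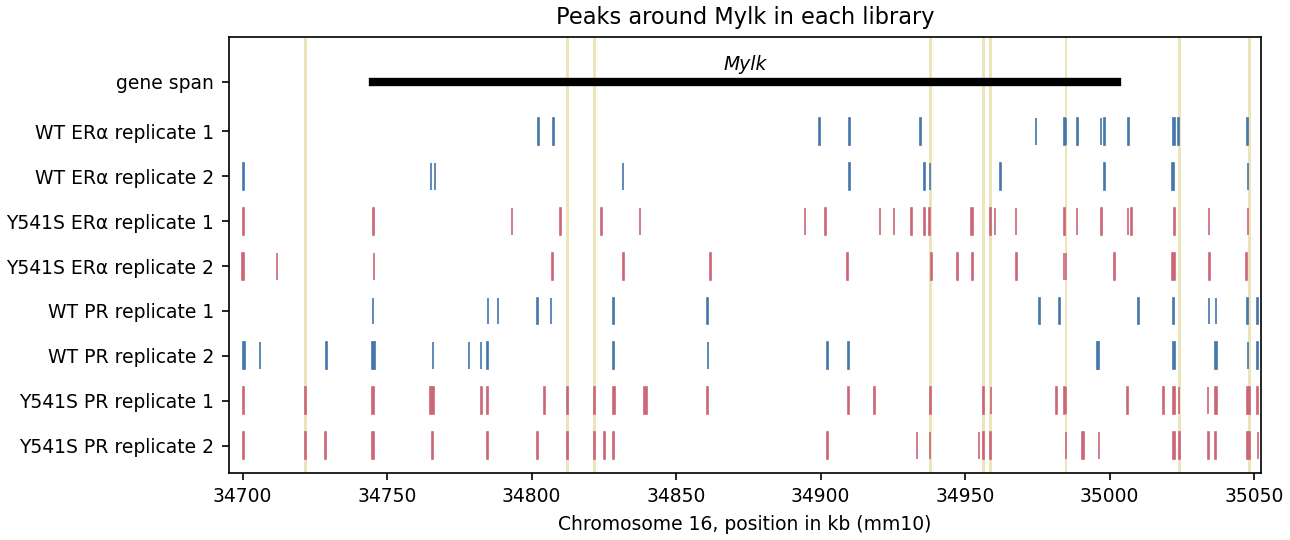
Position of every peak (coloured ticks, WT blue and Y541S red) in each of the 8 libraries around Mylk, with position on chromosome 16 in kb (mm10) on the x axis, libraries on the y axis and the gene span in black. Yellow bands mark the 9 PR regions present in both Y541S and neither WT PR library.

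Overlap between replicates and overlap between genotypes had overlapping ranges. Base-pair Jaccard indices averaged 0.298 between replicates of a group (range 0.209 to 0.447, 4 pairs) and 0.277 between genotypes of the same receptor (range 0.187 to 0.381, 8 pairs), the latter 0.282 for equal and 0.272 for unequal replicate numbers. Lists of different receptors in the same genotype averaged 0.193 (range 0.117 to 0.249), and lists differing in both 0.178 (range 0.131 to 0.231). These averages hide a difference between receptors. Replicates of PR reached 0.285 in WT and 0.447 in Y541S, but those of ERα only 0.209 and 0.251. Replicates of ERα were therefore not clearly more alike than the closest lists of different receptors. Of all 321963 regions formed from the 8 libraries together, 12113 had a peak in every library.

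ERα and PR shared many regions in both genotypes. Of the ERα regions found in both replicates, 56.2% overlapped a PR region found in both replicates in WT (95% Wilson interval 55.5 to 56.8%) and 62.6% did in Y541S (62.1 to 63.0%). Of PR regions, 32.3% overlapped an ERα region in WT and 37.4% in Y541S. These shares of the 2 genotypes are not measured against equal references: there were 42856 PR regions in WT and 70417 in Y541S, and 24742 and 42389 ERα regions. The same 19612 ERα regions shared by all 4 libraries overlapped a reproducible WT PR region in 61.9% of cases and a Y541S one in 78.9%. For Y541S-only ERα regions these values were 21.3% and 38.7%, and for WT-only ones 22.2% and 30.8%. Per library, 37.5 ± 1.86% of ERα peaks in WT and 41.3 ± 5.51% in Y541S overlapped a PR peak (SD, n = 2), a difference of 3.79 percentage points within the spread of the replicates (two-sided exact permutation p = 0.667). The difference was 8.998 points within replicate 1 and −1.42 within replicate 2, and it was −0.109 without Y541S ERα replicate 1 or without Y541S PR replicate 1. It was 7.69 without Y541S ERα or PR replicate 2, 2.48 without WT ERα or PR replicate 1 and 0.383 in equally long lists. With scaled coverage it was 20.7 points (exact permutation p = 0.667), from 22.8% and 67.5% in WT replicates 1 and 2 and 62.4% and 69.3% in Y541S. It rested on the WT replicate 1 pair. Without WT ERα replicate 1, which also removes its PR partner, it was −1.64 points, and without WT ERα replicate 2 it was 43.1. Scaling left 11454 PR peaks in WT replicate 1, against 56974 in WT replicate 2 and 49890 and 47353 in Y541S. The 22.8% was thus measured against a shorter PR list. The difference was 8.27 points at −log10 q of at least 1.3 and 16.2 at −log10 p of at least 5, where both Y541S values lay above both WT values (exact permutation p = 0.33 each, the smallest possible). In the other direction, 28.9 ± 4.25% of PR peaks in WT and 39.8 ± 2.47% in Y541S overlapped an ERα peak, at 31.9% and 41.5% within replicate 1 and 25.9% and 38.0% within replicate 2 (exact permutation p = 0.33, the smallest possible). This difference of 10.9 points came to 3.53 at −log10 p of at least 5 (exact permutation p = 1), 3.46 with scaled coverage (exact permutation p = 0.667) and 0.435 in equally long lists (exact permutation p = 1). In these settings the direction turned within replicate 1, from 32.8% in WT to 31.8% in Y541S, from 16.3% to 15.3% and from 27.9% to 26.2%.

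Y541S-only ERα regions coincided with Y541S-only PR regions at 746 places, against 401 for independent lists of 9803 and 13174 among 321963 regions (odds ratio 1.99, two-sided Fisher's exact p = 3.51e-58, in which regions are not independent replicates). Groupings that mixed the genotypes gave odds ratios of 1.58, 2.79, 2.02 and 1.74. The log2 odds ratio of 0.99 was 0.32 at −log10 p of at least 5 and turned to −0.55 in equally long lists, to −1.39 with scaled coverage, and to −0.90 and −0.59 without Y541S ERα replicate 1 or 2, and it was 0.08 without Y541S PR replicate 2 and 0.41 without Y541S PR replicate 1. Without a Y541S library, a Y541S-only region of that receptor needs a peak in 1 library only. For ERα their number rose from 9843 to 65263 and 59596. These left-out values concern another class of regions and cannot decide the direction.

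The position of peaks relative to genes was compared between genotypes over both receptors. Summits within 1 kb of either end of a coding gene made up 18.8 ± 0.794% of ERα peaks in WT and 14.2 ± 0.00965% in Y541S (SD, n = 2), and 13.6 ± 1.68% and 13.4 ± 1.21% of PR peaks. Within replicate 1 the WT and Y541S values were 18.2% and 14.2% for ERα and 12.4% and 12.5% for PR, and within replicate 2 they were 19.4% and 14.2%, and 14.8% and 14.2%. Outside genes lay 35.9 ± 1.03% and 40.5 ± 0.443% of ERα peaks and 38.6 ± 0.796% and 39.9 ± 0.459% of PR peaks. By class, 36.7% of shared, 10.2% of Y541S-only and 13.1% of WT-only ERα regions were at gene ends, and 18.3%, 7.60% and 7.91% of PR regions. Over both receptors the gene-end share differed by −2.41 points (two-sided exact permutation p = 0.167) and the share outside genes by 2.97 points (exact permutation p = 0.0556, the smallest possible). Both p-values treat ERα and PR libraries as independent, which the labels do not settle. The gene-end difference was −0.980 points at −log10 p of at least 5 and turned direction in equally long lists, to 1.24 points, and with scaled coverage, to 6.10 points. The difference in the share outside genes came to 0.948 points at −log10 p of at least 5 (exact permutation p = 0.33) and 0.494 points in equally long lists (exact permutation p = 0.889), where it was −0.455 for ERα and 1.44 for PR. With scaled coverage it turned to −2.50 points (exact permutation p = 0.444).

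A gene is called bound in a genotype where at least 1 linked region had a peak in both replicates, so a gene not called bound can still have regions in single libraries. Genes of estrogen response, fixed as a list of 30, were bound by ERα in 26 cases in WT and 30 in Y541S. Rhobtb3, Tfap2c, Areg and Ret met this definition in Y541S and not in WT, where Rhobtb3 had 5 ± 4.24 and Ret 4 ± 5.66 linked ERα regions per library (SD, n = 2). Of the list, 18 genes had a Y541S-only ERα region, against 19.7 in random lists matched on the number of linked regions, and 7 had a WT-only one. Slc9a3r1, a scaffold protein gene, had 7.50 ± 0.707 ERα regions per WT library and 16 ± 2.83 per Y541S library (SD, n = 2), Car12, a carbonic anhydrase gene, 9.50 ± 0.707 and 12.0 ± 0, and Siah2, a ubiquitin ligase gene, 4.50 ± 2.12 and 9 ± 4.24. For PR, 30 of 30 genes were bound in either genotype, and 22 had a Y541S-only region against 22.4 in matched lists, although 27 against 22.01 did at −log10 p of at least 5. Nrip1, a nuclear receptor corepressor gene, had 17.5 ± 2.12 PR regions per WT and 24.0 ± 8.49 per Y541S library. Per-gene differences stand beside an overall 1.55-fold (ERα) and 1.22-fold (PR) difference in list length, and no gene was tested alone.

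Genes of the progesterone paracrine list, 22 in number, were bound by ERα in 15 cases in WT and 19 in Y541S. Inhba, Lrp2, Wnt4, Areg and Igf2 had an ERα region found in both replicates in Y541S and not in WT, and Fgf10 the reverse, a difference that was not tested. Single WT libraries did have regions linked to these genes: Wnt4 had 7.50 ± 2.12 per WT and 9.50 ± 2.12 per Y541S library (SD, n = 2), and Igf2 2.50 ± 0.707 and 6 ± 1.41. Fgf10 had fewer in WT (4.50 ± 3.54) than in Y541S (7 ± 1.41). PR bound 20 of them in WT and 21 in Y541S, beside 79.0% and 84.2% of all coding genes, and Fgf10 had no PR region found in both replicates of either genotype. A Y541S-only region was near 12 genes for ERα (12.5 in matched lists) and 14 for PR (13.97). Adamts18, an extracellular protease gene, had 6 ± 1.41 ERα regions per WT and 15.5 ± 3.54 per Y541S library, and 3.50 ± 0.707 and 10.5 ± 2.12 PR regions. Prlr, the prolactin receptor gene, had 17.0 ± 4.24 and 28.5 ± 9.19 PR regions, and Nrg1, which encodes a ligand of ERBB receptors, 5.50 ± 2.12 and 10.5 ± 0.707. In the progestin and glucocorticoid response list of 18, ERα and PR each bound 17 genes in WT and 18 in Y541S, and Y541S-only regions were near 13 genes for ERα (12.7 in matched lists) and 16 for PR (13.7). Sgk1, a hormone-inducible kinase gene, had 13.5 ± 0.707 ERα regions in WT and 28.5 ± 4.95 in Y541S, and Fkbp5, which encodes a cochaperone of steroid receptors, 13.5 ± 0.707 and 21.0 ± 2.83. Zbtb16, a zinc finger transcription factor gene, had 35.0 ± 0 and 41.5 ± 7.78 PR regions.

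Among marker lists of mammary epithelium, hormone-sensing luminal genes were bound by ERα in 18 of 22 cases in WT and 21 in Y541S, Foxa1, Wnt4 and Areg being those with an ERα region in both replicates of Y541S and not of WT; Foxa1 had 2.50 ± 0.707 regions per WT and 5 ± 2.83 per Y541S library. PR bound 21 and 22 of them. Y541S-only regions were near 13 for ERα (12.6 in matched lists) and 19 for PR (16.3), and WT-only PR regions near 0, against 3.64 in matched lists. Cldn3, a tight junction gene, had 9.50 ± 3.54 and 18.0 ± 2.83 ERα regions per WT and Y541S library, and Krt19, a luminal keratin gene, 15 ± 0 and 18.0 ± 1.41 PR regions. In the luminal progenitor and alveolar list of 20, ERα bound 16 genes in WT and 17 in Y541S and PR 17 and 20, and Y541S-only regions were near 11 genes for ERα (10.8 in matched lists) and 15 for PR (12.5). Elf5, a transcription factor gene of alveolar cells, had 8.50 ± 0.707 and 15.5 ± 2.12 ERα regions, and the casein gene Csn1s2a had 4.00 ± 1.41 and 8.00 ± 1.41 PR regions. In the basal and myoepithelial list of 18, ERα bound 15 and 17 genes and PR 18 and 18, and Y541S-only regions were near 11 genes for ERα (11.4 in matched lists) and 12 for PR (12.5). Mylk had 9 Y541S-only PR regions, with 16.5 ± 2.12 PR regions per WT and 29 ± 2.83 per Y541S library, and Trp63, a basal cell transcription factor gene, had 5, with 12.0 ± 2.83 and 22.5 ± 0.707.

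Markers of fat, stromal and immune cells were counted in the same way. ERα bound 18 of 18 adipocyte genes in both genotypes, 13 of 16 fibroblast and endothelial genes in WT and 16 in Y541S, and 16 of 16 immune genes in WT and 15 in Y541S, where Ms4a1, a B cell gene, had 4 ± 1.41 linked regions per library but none found in both replicates. PR bound 16 and 17, 14 and 16, and 14 and 16 of them. Y541S-only ERα regions were near 13 of 18 adipocyte genes (12.6 in matched lists), 12 of 16 fibroblast and endothelial genes (10.1) and 11 of 16 immune genes (8.88). Y541S-only PR regions were near 9 (12.2), 13 (11.4) and 13 (10.04) of them. Retn, the resistin gene, had 7.50 ± 0.707 and 11.5 ± 0.707 ERα regions per WT and Y541S library, Fabp4, a fatty acid carrier gene of fat cells, 7.50 ± 0.707 and 11 ± 1.41, and Cd3e, a T cell receptor component gene, 7 ± 2.83 and 13 ± 2.83. Emcn, an endothelial sialomucin gene, had 2.50 ± 0.707 and 11.5 ± 3.54 PR regions, and Csf1r, a macrophage receptor gene, 8.00 ± 4.24 and 14.5 ± 0.707. The mean number of ERα regions was lower in Y541S for 1 adipocyte gene, 0 fibroblast and endothelial genes and 1 immune gene, and that of PR regions for 3, 2 and 2. Among the latter were Lep, the leptin gene, with 9.50 ± 0.707 and 7.50 ± 0.707 PR regions, and Itgax, with 4.50 ± 0.707 and 3.50 ± 0.707.

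Cell cycle genes, 26 in number, were all bound by ERα in both genotypes and by PR in 24 cases in WT and 26 in Y541S. Of these genes, 16 had a Y541S-only ERα region (15.5 in matched lists) and 19 a Y541S-only PR region (17.1). Cdk6, a G1 kinase gene, had 9 ± 1.41 and 20 ± 1.41 ERα regions per WT and Y541S library, and Mki67, a proliferation marker gene, 13.5 ± 0.707 and 17.5 ± 2.12 PR regions. Of 18 circadian clock genes, all bound by both receptors in both genotypes, 14 had a Y541S-only ERα region (13.1) and 15 a Y541S-only PR region (14.1). Rora, a nuclear receptor gene of the clock, had 41.0 ± 1.41 and 63.0 ± 4.24 ERα regions, and Clock 11.5 ± 0.707 and 19.0 ± 4.24 PR regions, whereas Per3, 1 of 2 clock genes with a lower ERα mean in Y541S, had 9.50 ± 3.54 and 6.50 ± 0.707 ERα regions. The PR mean was lower in Y541S for 4 clock genes. Of 20 nuclear receptor coregulator genes, ERα bound 17 in WT and 20 in Y541S and PR 20 in both, and 13 had a Y541S-only ERα region (15.5 in matched lists) and 12 a Y541S-only PR region (16.7). Tle3, a corepressor gene, had 18.0 ± 0 and 20.5 ± 2.12 ERα regions, and Ncoa2, a coactivator gene, 21.5 ± 3.54 and 30.5 ± 0.707 PR regions.

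With 10000 matched random lists per list, 0 of 24 combinations of list and receptor passed a Benjamini-Hochberg adjusted p of 0.05, and 1 was below 0.05 unadjusted: coregulators and PR, with fewer genes than in matched lists (permutation p = 0.0124, adjusted p = 0.298). Without WT PR replicate 1 it was 16 coregulator genes against 18.1 (permutation p = 0.211), and without each of the other PR libraries in turn 19 or 20 of 20 against 19.4 to 19.8 in matched lists, too near the list size to decide. The smallest adjusted p ran from 0.202 to 1 over 15 other settings. Fisher's exact test without matching also gave 0 adjusted and 2 unadjusted, hormone-sensing luminal (exact p = 0.0254) and progestin and glucocorticoid response (exact p = 0.0257), both for PR and above expectation. At −log10 p of at least 5, 2 were below 0.05 unadjusted, both for PR: estrogen response, with 27 genes against 22.01 (permutation p = 0.0388, adjusted p = 0.466), and coregulators, with 11 against 16.1 (permutation p = 0.0084, adjusted p = 0.202). With scaled coverage there were 3: ERα coregulators with 1 gene against 6.03 (permutation p = 0.0104, adjusted p = 0.250), ERα adipocyte genes with 2 against 6.52 (permutation p = 0.0348) and PR estrogen response with 20 against 14.3 (permutation p = 0.0444), both of the latter with an adjusted p of 0.355. For WT-only regions, 0 passed adjusted and 1 unadjusted, hormone-sensing luminal genes and PR (permutation p = 0.0292, adjusted p = 0.701). The example genes were those with most Y541S-only regions, a choice that favours higher numbers in Y541S. Of all 228 list genes, 208 had a higher and 12 a lower mean number of linked ERα regions in Y541S, and 176 and 38 of PR regions, with longer Y541S lists for both receptors. By count, the list with most members lower for PR was estrogen response, the longest list, with 8 of 30. Progesterone paracrine genes had a slightly larger share, with 6 of 22. Among all 21887 coding genes, 16360 were bound by ERα in WT and 17707 in Y541S, and 17300 and 18421 by PR.

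**Figure D4:**
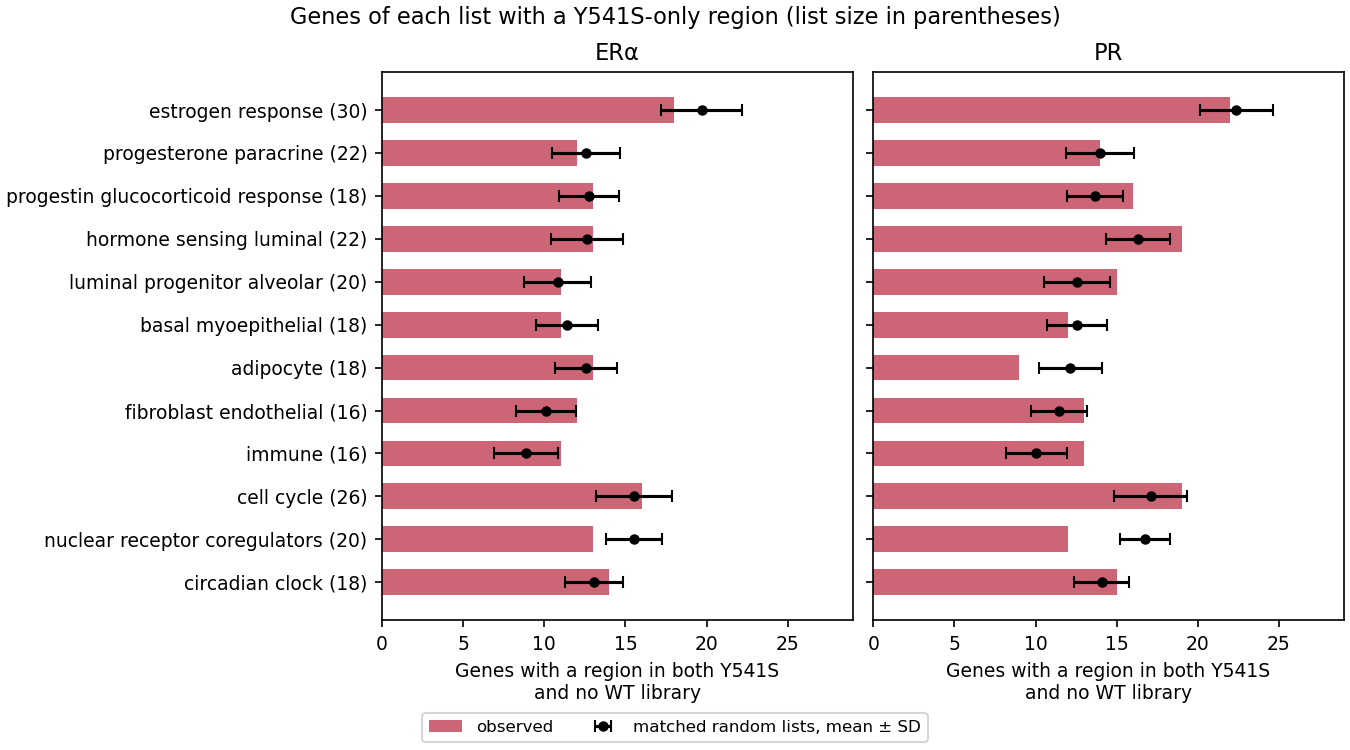
Number of genes in each list with a Y541S-only region (bars, x axis) for ERα and PR, with the mean ± SD of matched random lists (points); list sizes are in parentheses on the y axis. The farthest from its matched lists was coregulators and PR, 12 genes against 16.7.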

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

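The settings with scaled coverage, with regions carrying a peak of both receptors, with equally long lists or left-out libraries for gene ends and gene lists, with WT-only regions for gene lists, and all for the share outside genes, were chosen after the data were seen. Mean peak number kept its direction under all settings run, though not within replicate 2 of PR with scaled coverage (0.831-fold), at log2 0.42 to 0.72 for ERα and 0.20 to 0.93 for PR, and no design could pass 0.05. Leaving out 1 library gave 0.55–0.72 for ERα, 0.20–0.37 for PR and 0.42–0.50 for both. The motif settings were not run, for lack of a genome sequence.

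Replicate numbers were not shown to pair the libraries: deviations of same-numbered libraries correlated at 0.000514 to 0.0390. This check is weak, because most regions had a peak in a single library. That held for 156166 of 219945 ERα regions and 102454 of 192601 PR regions. The replicate numbers were also separate runs by the codes of the deposited files, so a pairing is not excluded. With the replicate block, exact permutation p-values became 0.5 for each receptor (log2 0.64 and 0.29), 0.125 for both (0.46) and 0.25 for gene ends (−2.41 points). No call could change, since neither these tests nor those without the block can give a p below 0.05. Within replicate number 1 alone, Y541S-only and WT-only regions numbered 66715 and 31710 for ERα and 62460 and 30048 for PR; within number 2 alone they numbered 78750 and 36725, and 45241 and 36517, and the co-occupancy difference was −1.42 points. These counts are larger by construction, since 1 library per genotype suffices.

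Y541S-only and WT-only ERα regions numbered 4386 and 586 at −log10 p of at least 5, 1445 and 697 in equally long lists and 1644 and 223 with scaled coverage; the WT-only count was 857 at −log10 q of at least 1.3. For PR, Y541S-only regions numbered 1284 in equally long lists and 5927 with scaled coverage, and WT-only regions 615 at −log10 q of at least 1.3, 245 at −log10 p of at least 5 and 21 with scaled coverage. With 1 library left out, the ranges were 13482–65263 (Y541S-only) and 2471–30042 (WT-only) for ERα and 19203–41764 and 1637–27880 for PR. The ratio of Y541S-only to WT-only regions stayed above 1 in the 8 other settings of each receptor (lowest 2.07 for ERα and 1.24 for PR). It was 0.639 and 0.507 without WT ERα replicate 1 or 2 and 0.742 and 0.953 without WT PR replicate 1 or 2. Without Y541S replicate 1 or 2 it was 15.9 and 24.1 for ERα and 9.04 and 25.5 for PR. With a library left out both counts are larger by construction. Regions of that genotype alone then need a peak in 1 library, and those of the other genotype still in 2. The ratio is therefore tilted by construction, and these settings cannot decide its direction.

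The co-occupancy difference ranged over −0.109–7.69 points with 1 library left out, and with scaled coverage over −1.64 (without WT ERα replicate 1) to 43.1 with 1 ERα library left out. Leaving out a library also removed its partner of the other receptor from this comparison. The share outside genes turned to −2.50 points with scaled coverage, and stayed at 2.61 to 3.34 with 1 library left out. The log2 odds ratio for coinciding Y541S-only regions ranged over −0.90–1.097 with 1 library left out (0.08 without Y541S PR replicate 2). Leaving out a Y541S library changes by construction which regions count as Y541S-only, so those values cannot decide its direction. The log2 odds ratio was −0.55 in equally long lists and −1.39 with scaled coverage, and the cause was not tested there. The gene-end difference was 1.24 points in equally long lists and 6.10 with scaled coverage, and −3.00 to −1.81 with 1 library left out. In the 15 other settings of the gene lists 0 passed, with smallest adjusted p-values of 0.202 to 1. With a library left out this says little of stability: the tests of the other receptor did not change, and without a Y541S library matched lists came near the list size (29.8 of 30 estrogen response genes without Y541S ERα replicate 1), leaving little room for an excess. Background coverage was below 3 reads in every library, so a place without a peak can hold signal that was not detectable at this depth.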

Other observations

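Depth and the coincidence of regions were tested with bounds set after the values concerned had been seen; the other bounds were set before.

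The genes with most Y541S-only regions were chosen after their values were seen, without matching on gene length. Lrmda, on chromosome 14 from 22019504 to 23056093, had 11 Y541S-only ERα and 12 Y541S-only PR regions, and Rad51b, a gene of recombination repair on chromosome 12, had 9 and 13. Csgalnact1, a gene of chondroitin sulfate synthesis, had 8 Y541S-only ERα regions, with 5 ± 0 ERα regions per WT and 23 ± 2.83 per Y541S library (SD, n = 2). Aopep had 16 Y541S-only PR regions, and Ptprk, a receptor phosphatase gene, 12, with 20 ± 5.66 and 37 ± 1.41 PR regions per WT and Y541S library. Arhgef28 had 12 Y541S-only PR and 0 Y541S-only ERα regions.

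The X chromosome was picked out among the chromosomes after the values were seen. It held 993.5 ± 57.3 ERα peaks in WT and 2100 ± 328 in Y541S (SD, n = 2), a fold of 2.10 beside 1.55 for all ERα peaks, with 1.96 within replicate 1 and 2.26 within replicate 2. For ERα alone the two-sided exact permutation p of 0.33 is the smallest possible. Its share of peaks was 1.46 ± 0.205% in WT and 1.98 ± 0.326% in Y541S for ERα and 1.72 ± 0.355% and 1.99 ± 0.173% for PR, with an exact permutation p of 0.111 over both receptors. Within replicate 2 the PR share was 0.947 times that of WT. X held 1.68% of the Y541S-only and 1.23% of the shared ERα regions, and 2.34% and 1.47% of those of PR. As a share of all regions on X, Y541S-only regions made up 3.69% for ERα, below the 4.23 to 4.83% of the autosomes, and 8.11% for PR, above their 6.29 to 7.81%, so the direction for ERα depended on the denominator.

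The longer Y541S lists were weighed against depth and against weak places lifted over the calling threshold. With coverage scaled to the shallowest library, the lower of the ERα folds within replicates was 1.34, which argues against depth, as measured by background coverage, as the whole reason for ERα. For PR the fold was 4.36 within replicate 1, although WT had the higher background coverage there (2.68 against 2.45 in Y541S). Within replicate 2, where WT had the lower one (0.927 against 1.35), the PR fold was 0.831. Greater depth of Y541S was thus not seen in replicate 1, but over both replicates depth and genotype cannot be told apart for PR. Of regions strong in both Y541S libraries, 0.357% had no WT peak for ERα, under the bound of 1% set for weak places. The 3.13% for PR fell between the bounds of 1% and 5% and left this open. These shares are over all strong regions, most of which had a WT peak. Of the Y541S-only regions themselves, 26 of 9843 for ERα and 929 of 13325 for PR were that strong. Of their ERα peaks, 42.8% and 36.2% reached −log10 p of 5 in Y541S replicates 1 and 2. This was near the 45.8% and 35.2% of the whole lists and below the 87.3% and 81.2% of shared regions. The median deposited fold of the strongest ERα peaks was 4.75 and 4.50 in WT replicates 1 and 2, and 5.41 and 5.16 in Y541S. For PR it was 5.67 and 7.75 in WT, and 11.9 and 8.94 in Y541S. Both Y541S values thus lay above both WT values for each receptor. These folds were not normalised across libraries. Either precipitation efficiency or binding could raise them, so they cannot tell these apart. Precipitation efficiency, which may differ between single libraries, and a genotype effect on binding remain untested.

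The lower share of Y541S ERα peaks at gene ends could come from added weak peaks away from genes. Equally long lists were expected to bring the difference under 1 point if so, and to leave it at −2 points or lower if not. It came to 4.03 points, 3.63 within replicate 1 and 4.42 within replicate 2, so the direction turned and neither bound was met. Among the 20000 strongest ERα peaks, 28.7% in WT and 32.8% in Y541S were at gene ends, against 18.8% and 14.2% of the whole lists. The lower Y541S share was thus carried by the weaker ERα peaks. Whether their number or their position carried it was not separated. Over both receptors the difference was still −0.980 points at −log10 p of at least 5, and the reason for the opposite direction among the 20000 strongest peaks was not tested.

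The coincidence of Y541S-only ERα and PR regions (odds ratio 1.99) may reflect a structure common to any grouping of the libraries, such as accessible places that pass the threshold in some libraries. Groupings that mixed the genotypes reached 2.79, as this explanation needs. A genotype effect on shared places is not excluded and was not separated from it.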
